A study of Mus musculus with 27 samples.

How the data were processed

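RNA was measured in liver tissue of wild-type C57/BL6J mice, with 27 libraries in 5 groups. The groups were sham operation, 24 h after 70% partial hepatectomy (PHx24), the same with etomoxir (PHx24_ETO), 48 h after resection (PHx48) and the same with etomoxir (PHx48_ETO). Groups and replicate numbers were taken from the sample labels. The labels describe treated mice but do not state that each library came from a separate animal, so p-values measure the spread between these libraries. They do not say whether the mice without etomoxir received a vehicle.

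Total RNA was extracted with TRIzol and polyadenylated RNA was made into libraries with the NEBNext Ultra kit, per the labels' protocols. The submitters' processing notes name CASAVA 1.8, fastp with no version, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, with the genome builds GRCm38 and mm10. The role of each tool, the annotation release and the strand setting of the counting are not given in the sources used here. The kit does not mark strand, so genes that overlap on either strand can share reads, and near-identical members of gene families (such as the serum amyloid A, Cyp4a, Cyp3a, Gstm, Mup and Ugt families) can take each other's reads or lose them. The values of such genes are uncertain.

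For each of 54532 genes the deposited table holds a raw read count per library, made by the authors. It also holds an FPKM value per library, computed by the authors from the counts. Tested on the table, the deposited FPKM equalled the count divided by the gene length and by a library size that was the median-of-ratios size factor times 16.512 (in units of 1e+06 counts). Within a library this library size varied by at most 7.1e-07 in relative terms. FPKM were therefore scaled between libraries to a typical gene and not to the library total. Gene length and coordinates came from the table. Of the gene IDs, 54495 were found in GENCODE M21 and 53585 had the same GRCm38 coordinates there. Symbols turned into dates (27 genes) and symbols shared with a gene of higher mean (103 genes) were set apart by gene ID.

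Total counts ranged from 14903757 to 18446372 per library. Library sizes behind the FPKM ranged from 12.97 to 20.46 (in 1e+06 counts). The biological coefficient of variation was 0.266, so the spread between livers and not the counting error set the precision of genes with many counts. The highest correlation of log2 values between 2 libraries of a group was 0.9875, and no library was a copy of another.

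Genes with an FPKM of at least 1 in at least 4 libraries were tested (12376 genes). The raw counts were analysed with edgeR 4.0.16 in R 4.3.3 (TMM factors, quasi-likelihood F test, all 27 libraries and 5 groups in 1 fit, Benjamini-Hochberg adjustment over the genes tested, call at an adjusted p under 0.05). Every adjusted p of a gene is from this test unless another is named. The SE of a log2 fold change was computed as its size divided by the square root of F. The design had been written for a table assumed to hold FPKM only, with limma on log2(FPKM + 1). Since the table also held counts, the count test became the main one and the limma fit an alternative. The design gave 5 comparisons, together with the difference between the etomoxir effects at 48 h and 24 h.

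Gene lists were fixed before the data were examined, as were the comparisons, the rule for naming genes and the alternative settings. They cover DNA replication, G1/S regulators, mitosis, ribosome biogenesis, mitochondrial fatty acid oxidation, PPARA targets, lipid droplet, fatty acid synthesis, cholesterol synthesis, bile acid, urea cycle and amino acid catabolism, gluconeogenesis, glycolysis, drug metabolism, acute phase, p53 targets, ATF4 and integrated stress response, NRF2 targets, unfolded protein response, oxidative phosphorylation, mitochondrially encoded genes, TCA cycle, growth hormone and STAT5 targets, clock, immediate early, interferon response, extracellular matrix and pericentral and periportal hepatocyte genes. Marker lists cover hepatocytes, Kupffer cells, monocytes, neutrophils, T and NK cells, B cells, sinusoidal endothelial cells, stellate cells and fibroblasts, cholangiocytes, erythroid cells, adipocytes, exocrine pancreas, gut epithelium, and mesothelium and gallbladder. Of their 654 genes, 653 were in the table and 565 were tested. A list of 12 skeletal muscle genes was added after the data were seen. Lists with at least 5 tested genes (35 lists) were tested against the other genes with camera of limma 3.58.1 on log2(FPKM + 1), with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. Beside it, camera with the correlation estimated per list and fry were run, and members called by edgeR were counted with the adjustment over all genes and over the list alone.

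Indexes for DNA replication, mitosis, mitochondrial fatty acid oxidation and PPARA targets were the mean log2(FPKM + 1) of the list's tested genes per library. They were compared by two-sided exact permutation tests, with Benjamini-Hochberg adjustment over the 20 tests. The smallest p these tests can give is 0.00126 for 7 against 5 libraries, 0.000583 for 7 against 7 and 0.00303 for 4 against 7.

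Genes were named by a fixed rule. It takes, for each comparison, the 6 largest called rises and falls (4 for the difference of the etomoxir effects) with a mean of at least 5 FPKM in the higher group, group ranges that did not overlap and a symbol that is no predicted or clone name, then up to 2 members of each list called by camera, of 6 lists named in every comparison (mitochondrial fatty acid oxidation, PPARA targets, DNA replication, mitosis, fatty acid synthesis, acute phase) and of each called marker list. Cpt1a, Ccnd1, Mki67, Cdkn1a, Fgf21, Pdk4 and Alb were always taken where tested. Genes outside the rule are named as such.

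The alternative settings were other scalings (median-of-ratios, equal totals as TPM, quantile), a pseudocount of 0.1, a filter of 0.1 FPKM and no filter, robust empirical Bayes, array weights, only the groups compared in the fit, an added minimum of 2-fold, the replicate block, and, for genes and indexes, each library left out in turn. TPM and quantile scaling, the pseudocount and the array weights were run in limma, since the count test takes none of them. Median-of-ratios scaling was not run for lists and indexes, as the deposited FPKM carry it. Alternatives added after the data were seen were DESeq2 1.42.0, the limma fit, FPKM rescaled to library totals for the indexes, log2 CPM and each library left out in turn for the lists, and leaving out 4 libraries with transcripts of other tissues or 2 libraries (PHx24 2 and PHx24_ETO 2) that stood apart. The gene, list and permutation tests were first run on simulated data. Of 100 genes changed 3-fold among 12376, edgeR recovered 85% for PHx24 and PHx48 vs sham and 92% for PHx48 vs PHx24. The etomoxir effects at 24 h and 48 h and their difference gave 88%, 83% and 72%. Of 100 changed 1.5-fold, 35%, 41%, 52%, 31%, 28% and 13% were recovered. Camera called 0 of 34 unchanged lists there, but a median of 11 or 12 in random library splits. Recovery in the real libraries may differ. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No reads were realigned, and isoforms were not analysed here.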

Results

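Gene expression was measured by RNA sequencing in 27 liver libraries of C57/BL6J mice. Partial hepatectomy removes 70% of the liver, after which the hepatocytes left behind enter the cell cycle and the organ regrows. Livers were sampled after sham operation (n = 5, time not given), 24 h after resection (PHx24, n = 7) and 48 h after resection (PHx48, n = 7). Further mice received etomoxir, an irreversible inhibitor of carnitine palmitoyltransferase 1, the enzyme that starts the transport of long-chain fatty acids into mitochondria. Etomoxir was injected into the peritoneum at 12.5 mg/kg 4 h before resection (PHx24_ETO, n = 4), and again 24 h after it in the mice kept to 48 h (PHx48_ETO, n = 4). The libraries held 14903757 to 18446372 counts. Albumin mRNA took 5.66 ± 1.98% of the counts in sham (SD, n = 5), 3.84 ± 0.755% in PHx24 (n = 7), 3.71 ± 0.721% in PHx24_ETO (n = 4), 5.93 ± 0.832% in PHx48 (n = 7) and 7.3 ± 0.756% in PHx48_ETO (n = 4). Transcripts of other tissues stood out most in 4 libraries: skeletal muscle genes in sham 1, PHx24 1 and PHx48 3, and pancreatic genes in sham 2. Counts are also given without these 4. Lower scores remained in other libraries, such as 2.67 for muscle in PHx48_ETO 4, 2.19 for pancreas in PHx24 3 and 2.34 for adipocyte in sham 3.

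**Figure D1:**
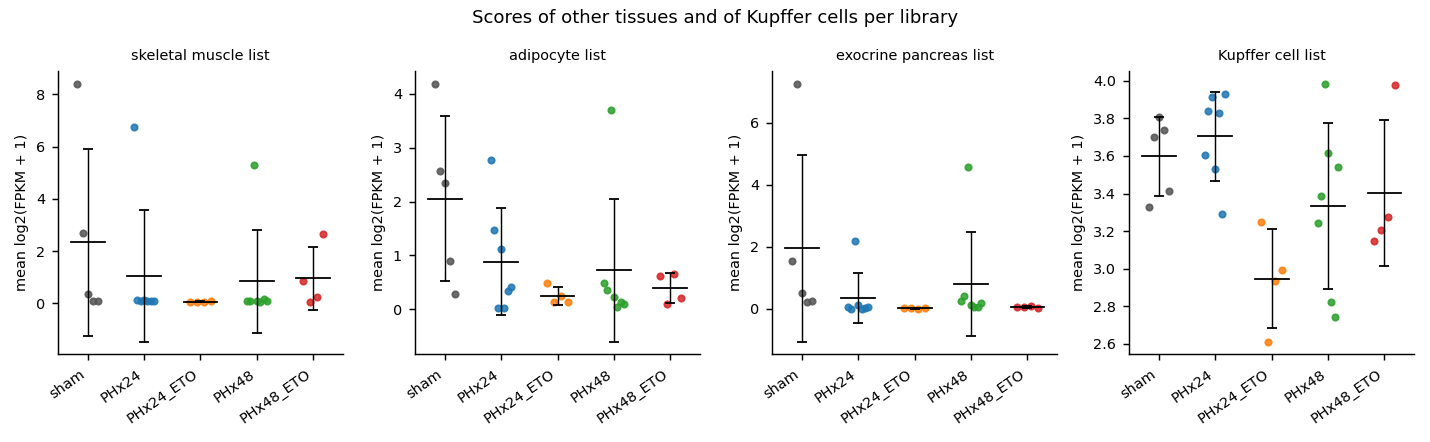
Mean log2(FPKM + 1) of the skeletal muscle, adipocyte, exocrine pancreas and Kupffer cell lists in every library, with the group mean (bar) and SD (whiskers), for sham (n = 5), PHx24 (n = 7), PHx24_ETO (n = 4), PHx48 (n = 7) and PHx48_ETO (n = 4). Single libraries carry the muscle and pancreas values, such as 7.26 for pancreas in sham 2.

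The PHx24 libraries were compared with sham to find what had changed 24 h after resection. The single genes that rose most were acute-phase genes. Lcn2, which encodes the iron-binding defence protein lipocalin 2 (ENSMUSG00000026822, GRCm38 chromosome 2, 32384633 to 32388252), rose from 2.16 ± 0.992 FPKM in sham (SD, n = 5) to 690.4 ± 154 FPKM in PHx24 (n = 7), a log2 fold change of 8.35 (SE 0.45, adjusted p = 1.4e-12 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Genes of DNA synthesis rose as well, among them Mcm5, a subunit of the replicative helicase, from 0.965 ± 0.287 to 20.5 ± 7.83 FPKM. Among the genes that fell were Car3, an abundant carbonic anhydrase, from 1245 ± 313 to 100.7 ± 55.8 FPKM, and Cyp8b1, the sterol hydroxylase needed for cholic acid, from 148.1 ± 14.1 to 12.4 ± 9.49 FPKM. In total 4326 of 12376 genes (35%) changed, 2366 higher and 1960 lower, and 697 and 468 of these by at least 2-fold.

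The naming rule gave as largest rises Lcn2, the serum amyloid genes Saa2 (log2 fold change 8.33) and Saa1 (6.33), whose reads cannot be fully separated, the MYB-family factor Mybl1 (5.98), the chromatin regulator Uhrf1 (5.33), which keeps DNA methylation through replication, and the mitotic kinase Pbk (4.97). The edgeR adjusted p of these 6 genes lay between 1.4e-12 and 6.08e-06. Each was higher in 7 of 7 libraries than in any sham library, which the naming rule requires. The largest falls were of the urinary protein gene Mup19 (-3.62), Car3 (-3.60), Cyp8b1 (-3.55), the selenium-binding protein gene Selenbp2 (-3.45), the carbonic anhydrase Car1 (-3.37) and the hepcidin gene Hamp2 (-3.30), with edgeR adjusted p from 6.46e-06 to 0.00165. The fall of Mup19 was smaller without sham 1 (-2.08, less than the other 5) and lost (adjusted p = 0.112) without the 4 libraries with transcripts of other tissues.

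Cell cycle genes rose at 24 h almost without exception. Of 29 DNA replication genes 28 rose (28 adjusted over the list alone, median log2 fold change 2.92), and Mcm2, another helicase subunit, rose by 3.42 (SE 0.374, edgeR adjusted p = 2.79e-07). All 29 mitosis genes rose (29 over the list alone, median 3.33), including Top2a, which untangles chromosomes (4.41), Ect2, needed for cytokinesis (3.47), and the proliferation marker Mki67 (3.83), at edgeR adjusted p of 1.25e-05, 1.2e-05 and 5.72e-05. Among 12 G1/S regulators 10 rose (10 over the list alone, median 1.60), with Ccne1, cyclin E1, up by 3.91. Ccnd1, cyclin D1, rose from 4.76 ± 2.57 FPKM (n = 5) to 41.4 ± 9.06 FPKM (n = 7). It overlaps Oraov1. Ribosome biogenesis genes rose in 16 of 20 cases (16 over the list alone, median 0.50), such as Nop56 (1.15, overlapping Idh3b) and Rrp12 (1.01), which process ribosomal RNA. The cell cycle inhibitor gene Cdkn1a rose by 1.84 (SE 0.315, edgeR adjusted p = 6.59e-05). Camera called these 4 lists with the preset correlation (camera adjusted p from 1.16e-18 to 9.87e-08). The adjusted p with an estimated correlation was 0.417 for DNA replication, 0.439 for mitosis, 0.286 for G1/S regulators and 0.417 for ribosome biogenesis. The DNA replication index rose from 1.19 ± 0.061 (n = 5) to 2.90 ± 0.474 (n = 7) and the mitosis index from 0.472 ± 0.126 to 1.86 ± 0.531, with adjusted p of 0.00631 and 0.00866 in the exact permutation tests.

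Some acute-phase, unfolded protein response and matrix genes rose in the same livers. Of 19 acute-phase genes 15 rose (15 adjusted over the list alone, median log2 fold change 1.55). Unfolded protein response genes rose in 11 of 16 cases and fell in 1 (12 and 1 over the list alone, median 0.66), with the chaperone genes Calr at 0.78 and Dnajb11 at 0.81 (edgeR adjusted p = 1.62e-05 and 5.46e-05). Extracellular matrix genes rose in 7 of 16 cases (7 over the list alone, median 0.60), including the matrix protease Mmp14 (1.16) and the protease inhibitor Timp1 (3.64, or 4.65 without sham 1); 4 rose without sham 4. Camera gave an adjusted p of 0.318 for acute phase and of 0.666 for both other lists with an estimated correlation. The call of extracellular matrix was also lost by fry and without sham 4, sham 5 or PHx24 2.

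Some genes of lipid and bile acid synthesis fell. Of 17 fatty acid synthesis genes 11 fell (13 adjusted over the list alone, median log2 fold change -0.68), among them Scd1, the desaturase that makes oleate, from 1042 ± 466 FPKM (n = 5) to 256.7 ± 151 FPKM (n = 7), and Dgat2, which completes triglyceride synthesis, by 0.74 (edgeR adjusted p = 0.000383 and 0.000123). Bile acid genes fell in 8 of 15 cases and rose in 2 (8 and 2 over the list alone, median -0.64), with the bile acid conjugating genes Slc27a5 at -1.20 and Baat at -0.88 (edgeR adjusted p = 1.63e-06 and 3.02e-05). Cholesterol synthesis genes fell in 3 of 22 cases and rose in 1 (2 and 0 over the list alone, median -0.41), Sc5d at -1.24 and Stard4 at -0.63. Growth hormone and STAT5 targets fell in 10 of 14 cases (10 over the list alone, median -1.25), with Serpina12, an adipokine gene, at -2.13. Oxidative phosphorylation genes fell in 19 of 29 cases (19 over the list alone, median -0.33), with the succinate dehydrogenase subunit Sdhb at -0.56 and the complex I subunit Ndufb8 at -0.42, the latter not called in TPM (adjusted p = 0.148 in limma). Interferon response genes fell in 9 of 16 cases and rose in 1 (9 and 1 over the list alone, median -0.72), with Ifit3 at -1.58 and Rsad2 at -0.99. The rising bile acid genes numbered 1 and the rising cholesterol genes 0 without sham 1, among other libraries. Camera called these 6 lists with the preset correlation, but the call of cholesterol synthesis was also lost by fry and without sham 4, sham 5 or PHx24 3, 6 or 7. Their adjusted p with an estimated correlation was 0.472 for fatty acid synthesis, 0.472 for bile acid, 0.748 for cholesterol synthesis, 0.417 for growth hormone and STAT5 targets, 0.595 for oxidative phosphorylation and 0.537 for interferon response.

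Mitochondrial fatty acid oxidation genes, the pathway that etomoxir blocks at its entry, fell in 5 of 20 cases at 24 h (4 adjusted over the list alone, median log2 fold change -0.18, a sign that turned to 0.027 in TPM). Without sham 1 the count was 8, and without sham 5 it was 3. Cpt1a, the liver form of the etomoxir target (ENSMUSG00000024900, chromosome 19, 3323301 to 3385732), fell from 64.2 ± 18.7 FPKM (n = 5) to 41.0 ± 4.71 FPKM (n = 7), a log2 fold change of -0.62 (SE 0.16, edgeR adjusted p = 0.00362), but was not called in TPM (adjusted p = 0.106 in limma). Etfa, which passes electrons from fatty acid oxidation to the respiratory chain, fell by 0.55 (edgeR adjusted p = 0.000757). PPARA targets, genes switched on by the fatty acid receptor of the liver, went both ways, with 5 of 23 higher and 6 lower (6 and 6 over the list alone, median -0.21 but mean 0.20; the median was 0.16 in TPM). Cyp4a14, a microsomal fatty acid hydroxylase, rose by 4.04 (5.17 without sham 5) and Fabp1, the fatty acid binding protein of liver, fell by 1.23 (edgeR adjusted p = 8.14e-05 and 4.74e-05). Neither index passed: the difference was -0.19 for fatty acid oxidation, with adjusted p = 0.129 in the exact permutation test (-0.23 and 0.0192 without PHx24 5), and 0.22 for PPARA targets, with adjusted p = 0.3. Fgf21 and Pdk4, both fasting genes, had edgeR adjusted p of 0.892 and 0.533. Albumin fell by 0.70 (edgeR adjusted p = 0.0142), a call lost without sham 4 or sham 5 (highest adjusted p = 0.0641), with no filter, in TPM and after quantile scaling (-0.19, limma adjusted p = 0.166).

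Rescaling to equal totals moved the median difference of all genes by 0.19, 0.33 and 0.14 in the comparisons of PHx24 with sham, PHx48 with sham and PHx48 with PHx24. Changes are therefore relative to the typical gene. In TPM, limma called 3797 genes higher and 896 lower in PHx24 than in sham, against 2366 and 1960 here. Without the 4 libraries edgeR called 1820 higher and 1615 lower.

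The PHx48 libraries were compared with sham in the same way. Mitotic genes made up most of the largest rises by edgeR, whereas Saa2 rose most of the named genes in the limma fits and without sham 3. Ccnb1, the cyclin that drives entry into mitosis (ENSMUSG00000041431, chromosome 13, 100778650 to 100786570), rose from 0.227 ± 0.185 FPKM in sham (SD, n = 5) to 20 ± 6.65 FPKM in PHx48 (n = 7), a log2 fold change of 6.50 (SE 0.774, edgeR adjusted p = 4.91e-07). Mki67 rose from 0.362 ± 0.11 to 13.5 ± 3.24 FPKM. The glutathione transferase gene Gstm3 rose from 71.2 ± 27.9 to 1076 ± 689 FPKM, although its reads cannot be fully separated from those of other Gstm genes. Serpina12 fell from 33.2 ± 11.7 to 2.75 ± 1.22 FPKM, and Hsd3b5, a male-biased steroid dehydrogenase, from 304.7 ± 65 to 30.8 ± 18.7 FPKM. Changed genes numbered 4513 (36.5%), 2410 higher and 2103 lower, 784 and 477 of them by at least 2-fold.

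Besides Ccnb1, the 6 largest rises were of the phosphatase gene Cdkn3 (log2 fold change 6.44), Saa2 (6.24), the ubiquitin-conjugating enzyme Ube2c (6.24), the spindle protein gene Hmmr (6.21) and Cdc20, an activator of the complex that ends mitosis (6.05). Cdc20 overlaps Elovl1. Without sham 4 Hmmr was at 7.26 and Cdc20 at 6.79. Their edgeR adjusted p lay between 1.67e-10 and 1.69e-06. The largest falls were of Serpina12 (-3.57), Hsd3b5 (-3.29), Cyp8b1 (-3.01), the collagen gene Col27a1 (-2.93), Hamp2 (-2.86) and the sulfotransferase gene Sult2a8 (-2.78), with edgeR adjusted p from 2.72e-11 to 0.00359. Each of the 12 genes differed in the stated direction in 7 of 7 libraries, which the naming rule requires.

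All 29 mitosis genes rose at 48 h (29 adjusted over the list alone, median log2 fold change 5.23), with Ccnb2 at 5.55 and the centromere histone Cenpa at 3.21 (edgeR adjusted p = 4.07e-08 and 2.67e-09). Of 29 DNA replication genes 28 rose (28 over the list alone, median 2.32), among them Gins2, part of the helicase (3.39, overlapping Gse1), and Chaf1a, which loads histones onto new DNA (3.43, overlapping Ubxn6). G1/S regulators rose in 9 of 12 cases (9 over the list alone, median 1.41), Ccne1 by 2.96 and Ccnd1 by 2.80. Ribosome biogenesis genes rose in 10 of 20 (10 over the list alone, median 0.29), such as Nop58 (0.98) and Utp20 (0.51). Camera gave an adjusted p with an estimated correlation of 0.269 for mitosis, 0.499 for DNA replication, 0.269 for G1/S regulators and 0.642 for ribosome biogenesis, which was also lost without the 4 libraries. The mitosis index rose by 2.94 and the DNA replication index by 1.47, each with adjusted p = 0.00631 in the exact permutation test.

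Some genes of the stress lists also rose at 48 h. Of 13 p53 targets 7 rose (7 adjusted over the list alone, median log2 fold change 0.72), including Mdm2, the ubiquitin ligase of p53 (0.72), and the nuclease gene Aen (1.27), at edgeR adjusted p of 1.36e-06 and 1.18e-06; Cdkn1a rose by 2.31. NRF2 targets, the oxidative defence genes, rose in 10 of 18 cases (13 over the list alone, median 0.77), Gstm3 by 3.93 and the quinone reductase Nqo1 by 2.27 (edgeR adjusted p = 1.42e-06 and 5.01e-05). Acute-phase genes rose in 9 of 19 cases and fell in 1 (12 and 2 over the list alone, median 0.64), with Lcn2 at 5.96 and 132.5 ± 64.5 FPKM (n = 7). Extracellular matrix genes rose in 6 of 16 (6 over the list alone, median 0.67), with Mmp14 at 1.09 and Timp1 at 3.09; without sham 1 the count was 10 and Timp1 at 4.11. Acute-phase genes numbered 13 higher without sham 3, and NRF2 targets 8 higher and 1 lower without PHx48 4. For these lists the adjusted p with an estimated correlation was 0.269 for p53 targets, 0.637 for NRF2 targets, 0.637 for acute phase and 0.642 for extracellular matrix, the latter also lost without sham 5.

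Some genes of hepatocyte function fell. Bile acid genes fell in 9 of 15 cases (9, and 1 higher, adjusted over the list alone, median log2 fold change -0.89), with Slc27a5 at -1.19 and Cyp27a1, which starts the alternative bile acid pathway, at -1.19 (edgeR adjusted p = 1.11e-06 and 2.38e-06). Growth hormone and STAT5 targets fell in 11 of 14 (12 over the list alone, median -1.51), such as Cyp2d9 (-1.44). Oxidative phosphorylation genes fell in 17 of 29 (18 over the list alone, median -0.30), Sdhb at -0.59 and Ndufb5, overlapping Mrpl47, at -0.57, but in TPM this median was 0.056 and 4 were higher and 0 lower. Of 14 hepatocyte genes 7 fell (7 over the list alone, median -0.33), with Apoh at -0.93 (overlapping Prkca) and Apoa1 at -0.76, while the median was 0.024 in TPM and 0.012 after quantile scaling. Interferon response genes fell in 7 of 16 (8 and 1 higher over the list alone, median -0.61), Irf7 at -1.38 (overlapping Phrf1) and Ifit1 at -1.78. Sinusoidal endothelial genes fell in 6 of 12 (6 over the list alone, median -0.53), Fcgr2b at -0.82 and Stab1 at -0.49 (overlapping Nt5dc2); 3 fell without sham 1 or without sham 2. The call of Stab1 was lost in TPM (-0.12, limma adjusted p = 0.578) and without the 4 libraries, and that of the hepatocyte list without sham 5. The adjusted p of camera with an estimated correlation was 0.269 for bile acid and for growth hormone and STAT5 targets, and 0.637 for the other 4 lists.

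Mitochondrial fatty acid oxidation genes fell in 9 of 20 cases at 48 h and rose in 1 (9 and 1 adjusted over the list alone, median log2 fold change -0.22, which was 0.15 in TPM with 5 higher and 3 lower). Etfdh, the next electron carrier after Etfa, fell by 0.76 (edgeR adjusted p = 1.22e-05). Cpt1a fell by 0.45 (edgeR adjusted p = 0.0272), a call lost without sham 3 or sham 5 (highest adjusted p = 0.115), with no filter, after quantile scaling and in TPM (-0.067, limma adjusted p = 0.781). The list had an adjusted p of 0.642 with an estimated correlation and was also lost without sham 5. Its index fell by 0.26, with adjusted p = 0.0309 in the exact permutation test, but passed neither with FPKM rescaled to library totals (-0.019, adjusted p = 0.686) nor without any of sham 3, sham 4, sham 5, PHx48 1 or PHx48 4, the smallest fall being 0.18. Of 23 PPARA targets 6 rose and 8 fell (6 and 10 over the list alone, median -0.14, which was 0.30 in TPM), with Acot3 at 2.60 and Cyp4a32 at -1.89, and the index differed by 0.017, with adjusted p = 0.924 in the exact permutation test. Fatty acid synthesis genes went both ways, with 8 of 17 higher and 2 lower (9 and 2 over the list alone, median 0.37). Acly, which makes cytosolic acetyl-CoA, rose by 1.44 and Dgat2 fell by 0.88 (edgeR adjusted p = 0.000308 and 1.29e-05). Between 4 and 5 rose without sham 2, 3 or 4, PHx48 3 or PHx48 5. Fgf21, Pdk4 and Alb had edgeR adjusted p of 0.0816, 0.325 and 0.523.

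In TPM, limma called 5687 genes higher and 655 lower in PHx48 than in sham, against 2410 and 2103 here. Without the 4 libraries edgeR called 1794 higher and 1711 lower.

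**Figure D2:**
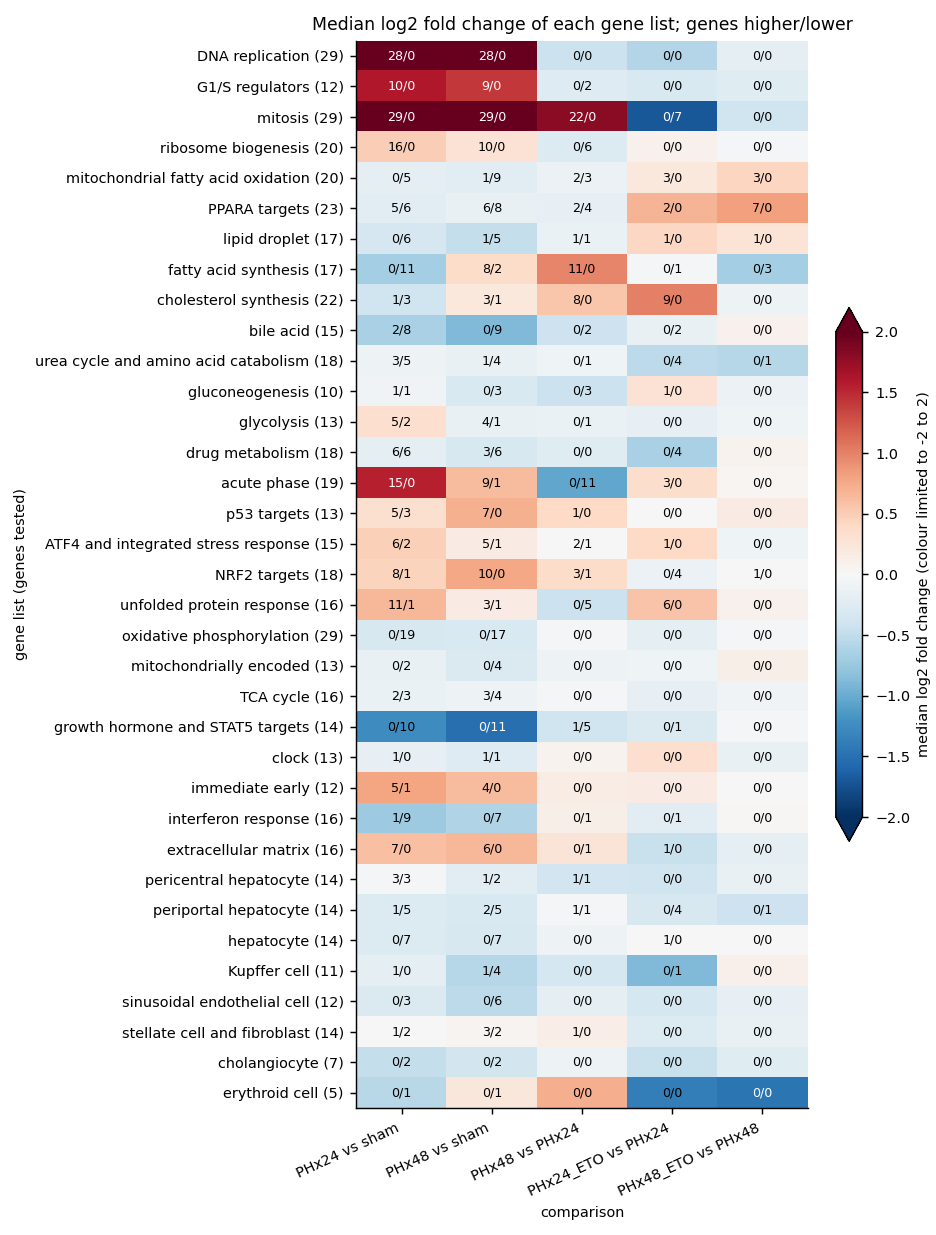
Median log2 fold change of each gene list with at least 5 tested genes (colour, limited to -2 to 2) in the 5 comparisons, with the number of its genes higher and lower by edgeR written in each cell as higher/lower and the number tested beside each list name. Mitosis genes were higher in 29 of 29 cases at both times after resection and lower in 7 with etomoxir at 24 h; medians near 0 in the first 3 columns depend on the scaling, such as that of mitochondrial fatty acid oxidation at 24 h, -0.18 here and 0.027 in TPM.

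PHx48 was then compared with PHx24 to follow regeneration from 24 to 48 h. Mitotic genes went on rising and acute-phase genes fell. Cdkn3 rose from 1.08 ± 0.73 FPKM in PHx24 (SD, n = 7) to 15.4 ± 2.43 FPKM in PHx48 (n = 7), a log2 fold change of 3.83 (SE 0.319, edgeR adjusted p = 1.57e-08). Chrna4, a nicotinic acetylcholine receptor subunit (ENSMUSG00000027577, chromosome 2, 181018380 to 181043546), rose 42.8-fold, from 0.333 ± 0.126 to 14.6 ± 13.5 FPKM. Lcn2 fell from 690.4 ± 154 to 132.5 ± 64.5 FPKM. Changed genes numbered 1435 (11.6%), 766 higher and 669 lower, 234 and 87 by at least 2-fold. In TPM limma called 1691 higher and 264 lower, and without the 4 libraries edgeR called 628 higher and 519 lower.

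Apart from these, the largest rises were of Ccnb2 (log2 fold change 3.36), the kinetochore gene Knstrn (3.20), the protease inhibitor gene Serpinb8 (3.18) and the lipase gene Pnpla3 (3.11), and the largest falls of Saa2 (-2.09), Saa1 (-1.68), the serum amyloid P gene Apcs (-1.62), the protease inhibitor gene Serpina3n (-1.62) and the oxygen sensor Egln3 (-1.58). Their edgeR adjusted p lay between 1.18e-07 and 0.00206, and each differed in the stated direction in 7 of 7 libraries. Of 29 mitosis genes 22 rose (27 adjusted over the list alone, median 1.81), with Cenpa at 2.14, whereas 0 of 29 DNA replication genes were called by edgeR (0 over the list alone, median -0.43). Camera called this list lower, but with adjusted p = 0.882 with an estimated correlation, and the call was also lost by fry, without the 4 libraries, and without PHx24 3, 4 or 6 or PHx48 2 or 3. Mcm6 and Prim1 had -0.91 and -0.73 (edgeR adjusted p = 0.0789 and 0.0799), and 2 replication genes fell without PHx24 2. The mitosis index rose by 1.55, with adjusted p = 0.00631 in the exact permutation test, and the DNA replication index differed by -0.25, with adjusted p = 0.294 (-0.39 and 0.0433 without PHx24 2). Among G1/S regulators 2 of 12 fell (2 over the list alone, median -0.26), Ccne1 by 0.95 and Cdk6 by 0.45, the latter lost in TPM (limma adjusted p = 0.121). The list call was lost with an estimated correlation (adjusted p = 0.723), by fry, without the 4 libraries, and without PHx24 3 or 4 or PHx48 3 or 7. Mki67, Ccnd1 and Cdkn1a had edgeR adjusted p of 0.0627, 0.458 and 0.281.

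Acute-phase genes fell in 11 of 19 cases between the times (16 adjusted over the list alone, median log2 fold change -1.03). Unfolded protein response genes fell in 5 of 16 (10 over the list alone, median -0.43), Calr by 0.71 and Sdf2l1 by 1.22 (edgeR adjusted p = 6.2e-05 and 0.000543), and ribosome biogenesis genes in 6 of 20 (9 over the list alone, median -0.27), Nop56 by 0.50 (lost in TPM, limma adjusted p = 0.0887) and Rrp9, overlapping Parp3, by 0.54. The latter count was 3 without PHx24 1. Some lipid synthesis genes rose: 11 of 17 for fatty acid synthesis (14 over the list alone, median 0.98), with the desaturase genes Fads2 at 1.13 and Fads1 at 0.85 (edgeR adjusted p = 1.04e-06 and 4.46e-06), and 8 of 22 for cholesterol synthesis (9 over the list alone, median 0.56), with Sc5d at 1.60 and Dhcr7 at 0.92. Of 13 p53 targets 1 rose, Bbc3 by 0.60 (3 over the list alone, median 0.40), and of 11 Kupffer cell genes 0 were called (0 over the list alone, median -0.36), with Vsig4 and C1qa at -0.52 and -0.47. The p53 count was 3 without PHx24 6, the cholesterol count 7 with 1 lower without PHx48 5, and 2 Kupffer cell genes fell without PHx48 3. Camera's adjusted p with an estimated correlation was 0.122 for mitosis, acute phase and fatty acid synthesis, 0.139 for p53 targets, 0.618 for unfolded protein response and ribosome biogenesis and 0.879 for cholesterol synthesis and Kupffer cell. The last 2 were also lost by fry, and Kupffer cell without PHx48 5 or 6.

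Fat oxidation genes moved in both directions from 24 to 48 h. Of 20 mitochondrial fatty acid oxidation genes 2 rose and 3 fell (2 and 3 adjusted over the list alone, median log2 fold change -0.12, which was 0.035 in TPM), with Acadm, the medium-chain acyl-CoA dehydrogenase, up by 0.52 and Acadvl, the very-long-chain one (overlapping Dvl2), down at -0.38 (edgeR adjusted p = 0.00198 and 0.00219), the latter lost in TPM (limma adjusted p = 0.0878). PPARA targets rose in 2 of 23 cases and fell in 4 (2 and 5 over the list alone, median -0.16), with Cyp4a10 at -1.80 and Cyp4a14 at -2.01 (edgeR adjusted p = 0.00757 and 0.0187); the call of Cyp4a14 was lost without PHx24 5 (adjusted p = 0.0559), and without PHx24 1 0 PPARA targets rose and 2 fell. The index differences were -0.077 and -0.20, with adjusted p of 0.318 and 0.171 in the exact permutation tests. Cpt1a, Fgf21, Pdk4 and Alb had edgeR adjusted p of 0.522, 0.167, 0.813 and 0.104.

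The effect of etomoxir at 24 h was measured by comparing PHx24_ETO with PHx24. Some lipid genes were higher and some drug-metabolising and mitotic genes lower. Retsat, a retinol saturase of fat cells and liver (ENSMUSG00000056666, chromosome 6, 72598475 to 72608425), rose from 75.5 ± 18.2 FPKM in PHx24 (SD, n = 7) to 181.8 ± 48.4 FPKM in PHx24_ETO (n = 4), a log2 fold change of 1.25 (SE 0.189, edgeR adjusted p = 0.00165). Cyp3a11, a main drug-oxidising cytochrome of mouse liver (ENSMUSG00000056035, chromosome 5, 145854426 to 145879964), fell from 1106 ± 170 to 339.2 ± 150 FPKM, and Gstm3 from 1218 ± 642 to 106.5 ± 75.7 FPKM. Ccnb2 fell from 4.83 ± 3.38 to 0.945 ± 1.25 FPKM. Changed genes numbered 359 (2.9%), 195 higher and 164 lower, 51 and 85 by at least 2-fold.

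The size of this response depended on single libraries and on the fit. The count was 1199 without PHx24_ETO 1, 138 without PHx24_ETO 2, 141 without PHx24_ETO 3, 167 without PHx24 4 and 181 without PHx24 3, and 0 by edgeR when the fit held only these 2 groups (smallest adjusted p = 0.0522), against 2401 genes at an unadjusted p under 0.05 in the fit of all groups and 764 by DESeq2. In TPM limma called 100 genes higher and 269 lower, and without the 4 libraries edgeR called 157 and 163.

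By the naming rule the largest rises were of Apoa4, an apolipoprotein of triglyceride-rich particles (log2 fold change 1.79), Angptl4, an inhibitor of lipoprotein lipase (1.63), Sqle, squalene epoxidase of cholesterol synthesis (1.51), the peroxisome gene Pex11a (1.28), Retsat (1.25) and the alanine transaminase Gpt2 (1.12). The largest falls were of Gstm3 (-3.53), the ethanolamine phosphate lyase gene Etnppl (-1.97), the cell cycle inhibitor Cdkn2d (-1.75), the glucuronosyltransferase Ugt1a9 (-1.73), which shares exons with other Ugt1a genes, Cyp3a11 (-1.72) and the phosphate transporter gene Slc17a4 (-1.60). Their edgeR adjusted p lay between 0.000523 and 0.0305, and each differed in the stated direction in 4 of 4 etomoxir libraries. Leaving out each library in turn kept the calls of Retsat, Gpt2 (0.62 without PHx24_ETO 2) and these 6 lower genes. Apoa4 was lost without PHx24 3, 4, 6 or 7 or PHx24_ETO 2, 3 or 4 (highest adjusted p = 0.0711), Angptl4 without PHx24_ETO 2 (0.0874), Sqle without PHx24_ETO 3 (0.0834) and Pex11a without PHx24_ETO 2 (0.0765, log2 fold change 0.52).

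Mitosis genes were lower with etomoxir at 24 h in 7 of 29 cases (28 adjusted over the list alone, median log2 fold change -1.69), including Ccnb2 (-2.33) and the spindle gene Nusap1 (-2.28, overlapping Oip5), at edgeR adjusted p of 0.0232 and 0.0267. The count was 29 without PHx24_ETO 1, 19 without PHx24 2, 2, 3, 1 and 2 without PHx24 3, 4, 6 and 7, and 0 without PHx24_ETO 2, 3 or 4. Each of these 3 omissions also cost the calls of Ccnb2 and Nusap1 (highest adjusted p = 0.0845 and 0.0911), and Nusap1 was lost without PHx24 6. Without PHx24_ETO 1 they were at -3.92 and -3.72. DNA replication genes were called in 0 of 29 cases by edgeR (0 over the list alone, median -0.59) and in 20 without PHx24_ETO 1, with Gins2 and Tyms at -1.10 and -0.92 (edgeR adjusted p = 0.0916 and 0.0937). Of 12 G1/S regulators 0 were called (1 over the list alone, median -0.31; 5 lower without PHx24_ETO 1), and Ccnd1, Mki67 and Cdkn1a had edgeR adjusted p of 0.387, 0.095 and 0.987. Camera's adjusted p with an estimated correlation was 0.251 for mitosis, 0.341 for DNA replication and 0.376 for G1/S regulators. The last 2 were also lost by fry, and G1/S regulators without PHx24_ETO 2 or 3. The mitosis index fell from 1.86 ± 0.531 (n = 7) to 0.803 ± 0.723 (n = 4), with p = 0.0242 and adjusted p = 0.0485 in the exact permutation test. That call did not hold without any of PHx24 1, 3, 4, 5, 6 or 7 or PHx24_ETO 2, 3 or 4, and the difference ranged from -1.41 to -0.87 when 1 library was left out. The DNA replication index differed by -0.63, with adjusted p = 0.202 in the exact permutation test, and passed without PHx24_ETO 1 (-1.03, adjusted p = 0.0455 in the exact permutation test).

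Some lipid genes rose with etomoxir at 24 h. Of 22 cholesterol synthesis genes 9 rose (19 adjusted over the list alone, median log2 fold change 1.01), with Srebf2, the transcription factor of the pathway, at 0.66 (edgeR adjusted p = 0.00741). The count was 17 without PHx24_ETO 1, 4 without PHx24 3, 4, 6 or 7 or PHx24_ETO 2, 5 without PHx24_ETO 4 and 1 without PHx24_ETO 3. PPARA targets rose in 2 of 23 cases (10 over the list alone, median 0.68; 6 without PHx24 5 or PHx24_ETO 1, 0 without PHx24_ETO 2) and mitochondrial fatty acid oxidation genes in 3 of 20 (5 over the list alone, median 0.21; 5 without PHx24 5 or PHx24_ETO 1, 0 without PHx24_ETO 2). Cpt1a rose from 41.0 ± 4.71 FPKM (n = 7) to 69.7 ± 18.3 FPKM (n = 4) and Acadl, the long-chain acyl-CoA dehydrogenase, by 0.52 (edgeR adjusted p = 0.0175 and 0.0117), both lost without PHx24_ETO 2 (adjusted p = 0.0736 and 0.0605). The PPARA target index rose by 0.58, with adjusted p = 0.0227 in the exact permutation test, but did not pass without PHx24 1, 3, 4 or 6 or PHx24_ETO 2 (0.35 without the last), and the fatty acid oxidation index differed by 0.20, with adjusted p = 0.171 in the exact permutation test (0.31 and 0.0208 without PHx24_ETO 2). Of 17 lipid droplet genes 1 rose (6 over the list alone, median 0.41), Plin4, which coats lipid droplets, at 2.95, a value carried by PHx24_ETO 2 (0.51 without it; adjusted p = 0.775). The call was also lost without PHx24 3, 4, 6 or 7 and in limma. In fatty acid synthesis 1 of 17 genes changed (1 over the list alone, median -0.036), the regulator Srebf1 at -1.44 (overlapping Rai1), lost without PHx24_ETO 2, 3 or 4 (highest adjusted p = 0.0777), and Fads2 had 0.40 (edgeR adjusted p = 0.107). Among the lists the adjusted p with an estimated correlation was 0.251 for cholesterol synthesis, PPARA targets and lipid droplet and 0.384 for fatty acid oxidation. The last was also lost by fry, and lipid droplet without PHx24_ETO 2.

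Some secretory genes rose too. Unfolded protein response genes rose in 6 of 16 cases (13 adjusted over the list alone, median log2 fold change 0.57), with the endoplasmic reticulum chaperones Pdia4 at 0.74 and Hsp90b1 at 0.66 (edgeR adjusted p = 0.0117 and 0.0185). The count was 11 without PHx24_ETO 1, 2 without PHx24 3, PHx24 4 or PHx24_ETO 4, and 0 without PHx24_ETO 3, when Pdia4 and Hsp90b1 were lost (highest adjusted p = 0.0679 and 0.0898). The fibrinogen genes Fgb and Fga rose by 1.25 and 1.24 (edgeR adjusted p = 0.00362 and 0.00623) among 3 of 19 acute-phase genes (5 over the list alone, median 0.35; 6 without PHx24_ETO 1). Atf4 was the only called member of 15 in the ATF4 and integrated stress response list (5 over the list alone, median 0.39), at 0.41, and was lost without PHx24 3, 4 or 6 or PHx24_ETO 2 or 3 (highest adjusted p = 0.147), with no filter and in TPM; 5 members rose without PHx24_ETO 1. The adjusted p with an estimated correlation was 0.251, 0.45 and 0.251 for these 3 lists. Acute phase was also lost by fry and without PHx24_ETO 3 or 4, and the ATF4 list without PHx24_ETO 2.

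Some genes of hepatocyte enzymes, and 1 Kupffer cell gene, were lower with etomoxir at 24 h. Of 18 drug metabolism genes 4 fell (7 adjusted over the list alone, median log2 fold change -0.65; 7 without PHx24_ETO 1, 2 without PHx24_ETO 2, 1 without PHx24_ETO 3), among them Ugt2b1 at -1.57, and of 18 NRF2 targets 4 fell (6 over the list alone, median -0.12; 2 without PHx24_ETO 3), with Gstm1 at -1.36 (edgeR adjusted p = 0.0139 and 0.00788). Ugt2b1 was lost without PHx24_ETO 2 or 3 (highest adjusted p = 0.0565). Urea cycle and amino acid catabolism genes fell in 4 of 18 cases (9 over the list alone, median -0.52; 9 without PHx24_ETO 1, 2 without PHx24 3 or 4, 1 without PHx24_ETO 2, 0 without PHx24_ETO 3), as did 4 of 14 periportal hepatocyte genes (5 over the list alone, median -0.33; 1 without PHx24_ETO 2, 0 without PHx24_ETO 3). Both lists hold Ass1, an enzyme of the urea cycle, at -0.98, lost without PHx24_ETO 3 (adjusted p = 0.0533), and the glutaminase Gls2 at -0.93 (overlapping Spryd4), lost without PHx24_ETO 2 or 3 (highest adjusted p = 0.0672). The bile salt export pump Abcb11 fell by 0.98 (SE 0.153, edgeR adjusted p = 0.00165) and the uptake carrier Slco1a4 by 1.18, the latter lost without PHx24_ETO 3 or 4 (highest adjusted p = 0.0692), among 2 of 15 bile acid genes (4 over the list alone, median -0.15; 1 without PHx24_ETO 3 or 4). Kupffer cell genes, those of the resident liver macrophages, fell in 1 of 11 cases (10 over the list alone, median -0.89; 7 without PHx24_ETO 1, 2 without PHx24 2 or 6, 0 without PHx24 3 or PHx24_ETO 2, 3 or 4): Cd5l by 1.30 (edgeR adjusted p = 0.0271, at most 0.0994 without 1 library), while C1qb had -0.89 (0.0604). Erythroid genes were called in 0 of 5 cases (5 lower over the list alone, median -1.39), with Hbb-bt at -1.68 and Alas2, overlapping Apex2, at -0.64. By camera the adjusted p with an estimated correlation was 0.251 for drug metabolism, NRF2 targets, urea cycle, periportal hepatocyte, Kupffer cell and erythroid cell and 0.283 for bile acid, which was also lost by fry and without PHx24_ETO 2. Alb was at -0.038 and the hepatocyte list at a median of 0.015.

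**Figure D3:**
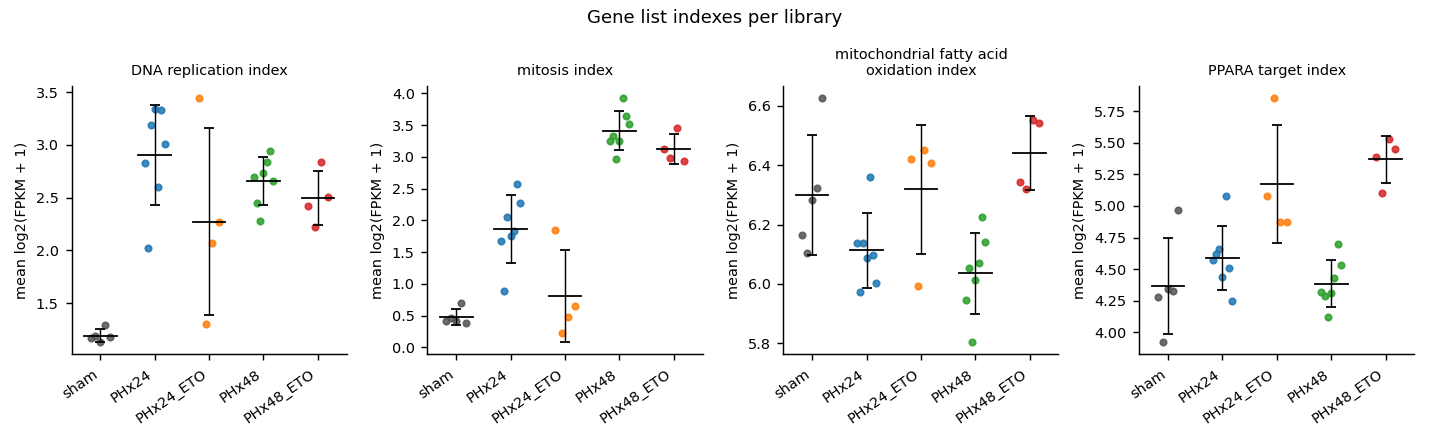
Index of each list (mean log2(FPKM + 1) of its tested genes) in every library, with the group mean (bar) and SD (whiskers), for the 5 groups (n = 5, 7, 4, 7 and 4). The mitosis index of PHx24_ETO spans 0.226 to 1.86, and each PHx48_ETO library lies above each PHx48 library for PPARA targets and for mitochondrial fatty acid oxidation.

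The effect of etomoxir at 48 h was measured by comparing PHx48_ETO with PHx48. Some genes of fatty acid oxidation rose and some of fatty acid synthesis fell. Cyp4a14 (ENSMUSG00000028715, chromosome 4, 115486200 to 115496142) rose from 58.3 ± 33.5 FPKM in PHx48 (SD, n = 7) to 452.2 ± 172 FPKM in PHx48_ETO (n = 4), a log2 fold change of 2.96 (SE 0.624, edgeR adjusted p = 0.037), and Ehhadh, the bifunctional enzyme of peroxisomal fat oxidation, from 83.7 ± 23.7 to 247.3 ± 52.8 FPKM. Scd1 (ENSMUSG00000037071, chromosome 19, 44394451 to 44407709) fell from 754.3 ± 326 to 145.8 ± 85.8 FPKM, and Acacb, the acetyl-CoA carboxylase whose product inhibits carnitine palmitoyltransferase 1, from 9.76 ± 4.67 to 2.87 ± 0.64 FPKM. Changed genes numbered 26 (0.21%), 16 higher and 10 lower, 7 and 6 by at least 2-fold.

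Besides Cyp4a14 and Ehhadh (log2 fold change 1.56), the largest rises were of Cyp4a10 (2.38), Cyp4a31 (1.83), the pantetheinase gene Vnn1 (1.32) and Retsat (1.23). The falls named were of Chrna4 (-3.45, from 14.6 ± 13.5 to 1.34 ± 0.631 FPKM), Scd1 (-2.37), Acly (-1.58), Ass1 (-1.16) and the lysosomal enzyme gene Naglu (-0.43). Their edgeR adjusted p lay between 0.00795 and 0.037, and each differed in the stated direction in 4 of 4 etomoxir libraries. PPARA targets rose in 7 of 23 cases (16 adjusted over the list alone, median 0.83), with Ech1 at 0.69 and Hsdl2 at 0.83, and mitochondrial fatty acid oxidation genes in 3 of 20 (14 over the list alone, median 0.44), with Acadm at 0.62 and Hadhb, a subunit of the trifunctional protein, at 0.57. Fatty acid synthesis genes fell in 3 of 17 cases (11 over the list alone, median -0.68), Acacb by 1.76. These 3 lists were also called by camera with an estimated correlation (adjusted p = 0.00569, 0.0329 and 0.0237). The PPARA target index rose from 4.39 ± 0.187 (n = 7) to 5.37 ± 0.186 (n = 4) and the fatty acid oxidation index from 6.04 ± 0.136 to 6.44 ± 0.125, each with adjusted p = 0.00866 in the exact permutation test and each higher in 4 of 4 libraries. Cpt1a had 0.55 (edgeR adjusted p = 0.302).

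Of 18 urea cycle and amino acid catabolism genes 1 fell, Ass1 (10 adjusted over the list alone, median log2 fold change -0.57), which was also the called member of 14 periportal hepatocyte genes (5 over the list alone, median -0.42). Lipid droplet genes rose in 1 of 17 cases (1 over the list alone, median 0.27), the monoglyceride lipase Mgll at 0.72. EdgeR called 0 of 29 mitosis genes (0 over the list alone, median -0.39, Aurka -0.51 and Cenpa -0.41) and 0 of 29 DNA replication genes (0 over the list alone, median -0.19, Uhrf1 -0.76 and Pold1 -0.47). The mitosis index differed by -0.29 and the DNA replication index by -0.16, with adjusted p of 0.199 and 0.318 in the exact permutation tests. Mki67, Ccnd1 and Cdkn1a had edgeR adjusted p of 0.991, 0.855 and 0.95, and Fgf21, Pdk4 and Alb of 0.706, 0.864 and 0.774. Acute-phase genes were called in 0 of 19 cases (0 over the list alone, median 0.045 but mean -0.16), with Saa3 at -1.47 and Orm3 at -0.89. Erythroid genes were called in 0 of 5 (4 lower over the list alone, median -1.45), with Hba-a2 at -1.74 and Hbb-bt at -1.51, and sinusoidal endothelial genes in 0 of 12 (0 over the list alone, median -0.16), with Lyve1 at -0.59 and Kdr at -0.34. Mitochondrially encoded genes were called in 0 of 13 (1 higher over the list alone, median 0.12). The adjusted p with an estimated correlation was 0.214 for urea cycle, 0.422 for periportal hepatocyte, 0.399 for lipid droplet, 0.806 for mitosis and sinusoidal endothelial cell and 0.522 for erythroid cell and mitochondrially encoded genes. Each of these was also lost by fry, lipid droplet without PHx48_ETO 4, erythroid cell without PHx48 1 or 2 or PHx48_ETO 1, and sinusoidal endothelial cell without PHx48 2 or 3 or PHx48_ETO 1, 2 or 3.

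Most of the 26 calls lay close to the threshold. The count was 1 without PHx48_ETO 3, which left Retsat, 3 without PHx48_ETO 1, 7 without PHx48 7, 12 without PHx48 1, 13 without PHx48 3 or PHx48_ETO 2, 14 without PHx48 6, 15 without PHx48_ETO 4 and 16 without PHx48 5. Of 17 named and called genes 16 lost the call without at least 1 library (highest adjusted p = 0.164), while the log2 fold change ranged from 2.79 to 3.24 for Cyp4a14 and from -2.86 to -2.18 for Scd1. With no filter on low values edgeR called 11 genes, and Cyp4a14, Cyp4a10, Ehhadh, Vnn1 and Scd1 were among the calls lost. With only these 2 groups in the fit it called 33, 15 of them shared, and Acacb, Acly, Chrna4, Ech1 and Naglu were lost. Called PPARA targets, with 1 library left out, numbered 0 to 5 against 7, fatty acid oxidation genes 0 to 3 against 3, and fatty acid synthesis genes 0 to 5 against 3, each 0 without PHx48_ETO 3. In TPM limma called 12 genes higher and 18 lower, DESeq2 called 68, and without the 4 libraries edgeR called 20 higher and 10 lower.

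**Figure D4:**
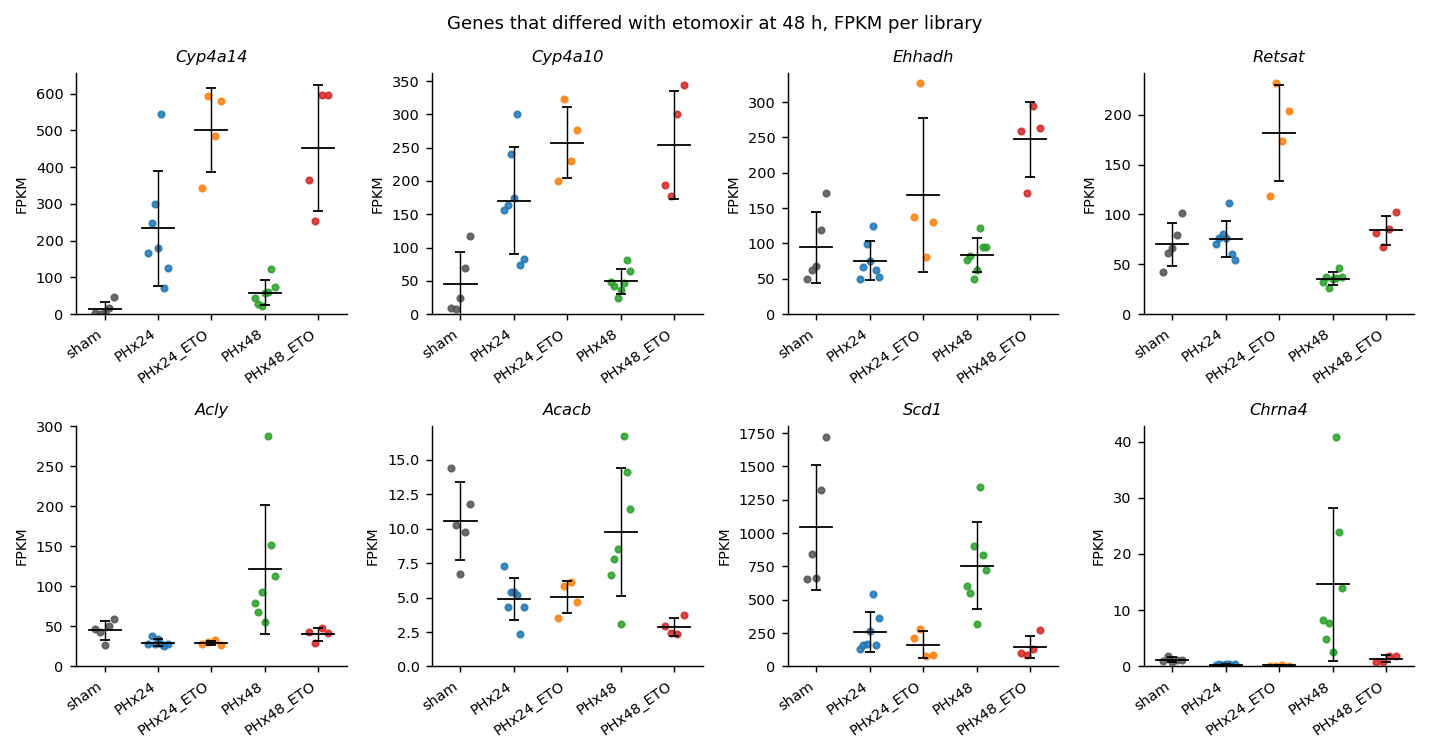
FPKM of 8 genes called between PHx48_ETO and PHx48 in every library, with the group mean (bar) and SD (whiskers), for the 5 groups (n = 5, 7, 4, 7 and 4). Cyp4a14, Cyp4a10, Ehhadh and Retsat are higher and Acly, Acacb, Scd1 and Chrna4 lower in PHx48_ETO than in PHx48, as for Scd1 with 145.8 ± 85.8 against 754.3 ± 326 FPKM.

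The etomoxir effect at 48 h, after a further dose, was compared with that at 24 h, so time and dose are confounded. It differed for 2 of 12376 genes by edgeR, both cytochromes of drug metabolism: Cyp3a11 by 1.89 on the log2 scale (SE 0.309, edgeR adjusted p = 0.0121) and Cyp3a59 (ENSMUSG00000061292, chromosome 5, 146079257 to 146113287) by 1.77 (SE 0.276, edgeR adjusted p = 0.0116). The reads of these neighbours cannot be fully separated. Both calls were lost without PHx24_ETO 4 (adjusted p = 0.0763 and 0.0724) and without PHx24 2 and PHx24_ETO 2 together, Cyp3a59 also in TPM (limma adjusted p = 0.163), and the count was 239 without PHx24_ETO 1, 0 without PHx24_ETO 4, and 42 by DESeq2, against 1064 genes at an unadjusted p under 0.05. Ccnb2, Acacb, Acly and Fgb had differences of 2.31, -1.78, -1.55 and -1.19 (edgeR adjusted p from 0.215 to 0.279), and Cpt1a of -0.19 (0.841). Of 18 drug metabolism genes 1 was called (4 higher adjusted over the list alone, median 0.72; 6 without PHx24_ETO 1), of 22 cholesterol synthesis genes 0 (15 lower over the list alone, median -1.07; 6 without PHx24_ETO 1), of 11 Kupffer cell genes 0 (10 higher over the list alone, median 0.97) and of 29 mitosis genes 0 (0 over the list alone, median 1.34; 24 higher without PHx24_ETO 1). The adjusted p of camera with an estimated correlation was 0.197, 0.246, 0.197 and 0.34 for these lists, each also lost by fry. No index was called: DNA replication differed by 0.47, mitosis by 0.77, fatty acid oxidation by 0.20 and PPARA targets by 0.40. Permutation p was 0.319, 0.15, 0.303 and 0.361 (adjusted p = 0.361 for each), which does not exclude a difference.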

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

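The tests of the lower mitosis index, of the higher PPARA target index and of the transcripts of other tissues were chosen after the results were seen, whereas the splits of the libraries and both correlations between responses were set before. Single libraries that stood apart from their group were found by Dixon's test, which picks about 1 in 20 groups by chance. It picked 23 of 175 groups over 35 measures, where 8.75 would arise by chance.

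The mitosis index was lower with etomoxir at 24 h, and 3 explanations were weighed. Without PHx24_ETO 2, an unusual library in other measures, the difference was -0.87 (-1.06 with it), larger than the SD of the PHx24 libraries (0.531), and 2 of the other 3 etomoxir libraries lay below each PHx24 library, which argues against that library as the whole cause. The call itself ended (exact permutation p = 0.0667): the difference shrank, and PHx24_ETO 1, at 1.86, lay at the mean of the PHx24 libraries. Fewer hepatocytes would raise the genes of every other liver cell type, yet the 5 lists of such cells had a median difference of -0.56 (range -1.29 to -0.31), 0 of 5 were higher, and the hepatocyte list differed by 0.027 (exact permutation p = 0.658). A delay of mitosis made up by 48 h stays open. The difference was -1.06 at 24 h and -0.29 at 48 h, after a further dose. The change between the times had an exact permutation p of 0.15.

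The PPARA target index was higher with etomoxir at 48 h. Reads shared within the Cyp4a and Acot families do not explain it, because the 15 genes left without those families still differed by 0.71 (exact permutation p = 0.00303, the smallest these groups can give). Rescaling to library totals gave 0.96 (exact permutation p = 0.00303), which argues against the scaling. A fasting-like state could raise the same genes, but the gluconeogenesis list differed by -0.19 (exact permutation p = 0.297), so this stays open, as food intake is not given in the sources used here. An effect of etomoxir itself on these genes stays open, and how it would arise was not tested.

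Skeletal muscle, fat and pancreas genes were high in a few libraries. Sham 1, PHx24 1 and PHx48 3 held 1826, 811.7 and 231.8 FPKM of Acta1, the actin of skeletal muscle, against a median of 0.018 FPKM in the others, and 100% of 12 muscle genes were at least 4 times the median of the others in each of the 3. Muscle taken with the liver is a candidate source that stays open, since the list was added after these genes were seen, and no biological explanation was tested. These libraries did not set the response to resection, since 3435 genes changed between PHx24 and sham without the 4 libraries, against 4326 with them. The skeletal muscle score was 6.76 in PHx24 1 (0.078 to 0.13 in the others of its group) and 5.31 in PHx48 3 (0.061 to 0.16), with 2.67 in PHx48_ETO 4 (0.046 to 0.87), and the adipocyte score was 3.69 in PHx48 3 (0.031 to 0.48). The exocrine pancreas score was 7.26 in sham 2 (0.21 to 1.55), 2.19 in PHx24 3 (0 to 0.12) and 4.56 in PHx48 3 (0.047 to 0.41).

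PHx24_ETO 1 stood apart from the other 3 libraries of its group in the direction of the untreated livers. It held 4.54 FPKM of Mki67 (0.0364 to 0.726 in the others), 1.91 FPKM of Ccnb1 (0 to 0.128), 2.81 FPKM of Ccnb2 (0.199 to 0.575) and 107.9 FPKM of Car3 (16.2 to 25.7). Its PPARA target index of 5.08 lay above those of PHx24_ETO 3 and 4 (4.87 and 4.88) and level with the highest PHx24 library, and its Cpt1a of 86.9 FPKM above every PHx24 library (35.1 to 46.3). A missed injection or a wrong label could make a library resemble the untreated ones and was not tested, and it would change what the etomoxir values at 24 h mean (359 genes with this library, 1199 without it). In PHx24_ETO 2 the fatty acid oxidation index was 5.99 (6.41 to 6.45 in the others) and Alb 19160 FPKM (14940 to 15540), and in PHx24_ETO 3 Chrna4 was 0.316 FPKM (0.106 to 0.135). The fatty acid oxidation index was 6.36 in PHx24 5 (5.97 to 6.14 in the others). Sham 4 had a mitosis index of 0.69 (0.39 to 0.46), with 0.549 FPKM of Ccnb1 (0.0978 to 0.217) and 1.66 FPKM of Ccnb2 (0.797 to 1.03). PHx48_ETO 3 held 259.8 FPKM of Lcn2 (114.7 to 134.3), 17.4 FPKM of Mki67 (11.1 to 12.2) and 18.7 FPKM of Sqle (8.96 to 10.5). Serpina12 was 4.08 FPKM in PHx48_ETO 4 (1.63 to 2.02), Acly 287.7 FPKM in PHx48 5 (55.4 to 152.1) and Gstm3 2516 FPKM in PHx48 4 (526.6 to 1358).

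The etomoxir effect differed between the times for Cyp3a11 by 1.89 and for Cyp3a59 by 1.77 on the log2 scale, and for 20 lists by camera with the preset correlation, of which 0 were called with an estimated correlation and 1 by fry. Chance could not be excluded for the 2 genes: in 100 splits of the etomoxir and untreated libraries, 5 called at least 2 genes, the real split included. The highest other called 334, with PHx24 2 on the side of PHx24_ETO 2, 3 and 4. A count this far above the real one points to a structure of the samples, whose source was not tested. The 20 lists were reached by 2 of 100 splits, the real one included (other splits: median 12, highest 21), so chance stays open.

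Library splits into groups of the real sizes, 100 per comparison, tested chance for the numbers of changed genes. The real count was reached only by the real split for PHx24 against sham (4326; highest other 1701), PHx48 against sham (4513; highest other 2079), PHx48 against PHx24 (1435; highest other 44) and PHx48_ETO against PHx48 (26; highest other 5), so 1 of 100 in each. The 359 of PHx24_ETO against PHx24 was reached by 4 of 100 splits, the real one included, so chance stays open. The highest other called 603 and set PHx24 2, PHx24 5, PHx24_ETO 2 and PHx24_ETO 3 against the rest, so part of the spread between these libraries did not follow the treatment. Camera's preset correlation called many lists in random splits as well. List counts were reached by 41 of 100 splits for PHx24 against sham (13, highest other 19) and 30 for PHx48 against sham (15, 22). Of 100 splits 62 did so for PHx48 against PHx24 (10, 19) and 71 for PHx48_ETO against PHx48 (10, 21), so chance was not excluded. For PHx24_ETO against PHx24 only the real split reached 25 (1 of 100), but another reached 23, so chance stays open.

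A move toward sham with etomoxir at 24 h was neither shown nor excluded across all genes. Over 35 halvings of the PHx24 libraries the etomoxir and resection responses had a median correlation of 0.014 (-0.117 to 0.144, permutation p = 0.952, 330 permutations). The etomoxir responses at 24 h and 48 h were correlated across 12376 genes (r = 0.306, exact permutation p = 0.0345, 108900 permutations). Without 1 library r ranged from 0.217 to 0.389, and p was 0.0592 without PHx24 4, 0.0754, 0.0516 and 0.0519 without PHx24_ETO 1, 3 and 4, and 0.145 and 0.115 without PHx48_ETO 1 and 2.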

How the results depend on the processing

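DESeq2, rescaling to library totals, leaving out 4 or 2 libraries together and, for lists, single ones were chosen after the results were seen. Causes of the changes below were not tested.

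Counts of changed genes were 4326, 4513, 1435, 359, 26 and 2 for PHx24 against sham, PHx48 against sham, PHx48 against PHx24, etomoxir at 24 h, etomoxir at 48 h and the difference of the etomoxir effects. With a log2 fold change of at least 1 the first 5 were 1165, 1261, 321, 136 and 13. Array weights in limma gave 2593 for PHx48 against PHx24, 2132 and 51 for etomoxir at 24 h and 48 h and 186 for the difference. DESeq2 gave 764 (371 higher, 393 lower) and 68 (33 and 35) for etomoxir and 42 (20 and 22) for the difference. Without a filter etomoxir changed 196 genes at 24 h and 11 at 48 h, and with FPKM of at least 0.1 it changed 11 at 48 h. With only the groups compared in the fit edgeR called 0 at 24 h. Blocking on replicate number gave 44 at 48 h (32 and 12, 19 shared). Same-number libraries had r of -0.232 to 0.655, so pairing is unclear. The block ended the calls of Ccnb2, Nusap1, Plin4, Atf4, Igf1, Cxcl10 and Srebf1 at 24 h, and of Acly, Acacb and the mitosis list at 48 h, with etomoxir, and gave others. TPM gave 1 gene for the difference. Without PHx24 2 and PHx24_ETO 2 there were 202 at 24 h and 0 for the difference. Leaving out 1 library gave 3853 to 4291, 4101 to 4415, 1134 to 1443, 138 to 1199 (without PHx24_ETO 2 and PHx24_ETO 1), 1 to 25 (without PHx48_ETO 3 and PHx48 4) and 0 to 239 (without PHx24_ETO 4 and PHx24_ETO 1).

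Lists called by camera with the preset correlation numbered 13, 15, 10, 25, 10 and 20 in the same order. Estimating the correlation left 0, 0, 0, 0, 3 and 0. The self-contained test fry called 12 and 3 for etomoxir at 24 h and 48 h and 1 for the difference. Leaving out 1 library gave 11 to 17, 12 to 17, 8 to 14, 14 (without PHx24_ETO 2) to 26, 8 to 14 and 15 to 22.

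The mitosis index difference with etomoxir at 24 h (-1.06) did not pass after quantile scaling (-0.97, exact permutation adjusted p = 0.0551), rescaling to totals (-1.07, 0.053), without the 4 libraries (-1.09, 0.0779) and without PHx24 2 and PHx24_ETO 2 (-1.03, 0.0866), and ranged from -1.41 to -0.87 without 1 library. The PPARA target index at 24 h (0.58) did not pass after rescaling to totals (0.54, 0.0606), without the 4 libraries (0.58, 0.0529) and without PHx24 2 and PHx24_ETO 2 (0.36, 0.139), and ranged from 0.35 to 0.68. The fatty acid oxidation index at 24 h (0.20) passed after quantile scaling (0.23, 0.0364), without PHx24 2 and PHx24_ETO 2 (0.29, 0.0298) and without PHx24_ETO 2 (0.31), and ranged from 0.16. In PHx48 against sham this index (-0.26) did not pass as a median over the list (-0.11, 0.516) and after rescaling to totals (-0.019, 0.686), and ranged from -0.31 to -0.18. In PHx24 against sham it ranged from -0.24 to -0.11 and passed without PHx24 5 (-0.23). The DNA replication index passed between PHx48 and PHx24 without PHx24 2 and PHx24_ETO 2 (-0.39, 0.0455), ranging from -0.39 to -0.17, and with etomoxir at 24 h without PHx24_ETO 1 (-1.03), ranging to -0.31. At 48 h with etomoxir the indexes ranged from 0.93 to 1.07 for PPARA targets, 0.36 to 0.44 for fatty acid oxidation, -0.40 to -0.21 for mitosis and -0.28 to -0.07 for DNA replication.

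Apoa1 in PHx48 against sham changed sign after quantile scaling (0.18, limma adjusted p = 0.264). With etomoxir at 24 h ribosome biogenesis turned lower without PHx24 2 and PHx24_ETO 2 (camera adjusted p = 0.828) and interferon response turned higher without PHx24_ETO 2 (camera adjusted p = 0.942, 0.00112 to 0.942 without 1 library). In the difference of the effects ribosome biogenesis turned higher without the same 2 libraries (camera adjusted p = 0.975) and pericentral hepatocyte lower without PHx24_ETO 2 (camera adjusted p = 0.809, 0.000181 to 0.809 without 1 library).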

Other observations

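The lists and genes below were looked at after the main results, and their tests were not chosen in advance. Some genes of neutrophils and monocytes were higher at 24 h than in sham and at 48 h. The alarmin gene S100a8, abundant in neutrophils, rose by 3.32 in PHx24 against sham and fell by 2.74 from 24 to 48 h, S100a9 by 2.83 and 2.96, and the monocyte attractant Ccl2 by 3.96 and 2.26. Of 2 tested neutrophil genes 2 rose at 24 h, and of 4 monocyte genes 2 rose and 1 fell; 2 of each list fell from 24 to 48 h. PHx24 2 stood apart, with a neutrophil score of 5.20 (1.56 to 2.58 in the others of its group) and a monocyte score of 4.01 (2.21 to 3.11). Without it 2 neutrophil genes still rose and fell, and 1 monocyte gene fell from 24 to 48 h. Some glucose genes shifted as well: Pklr, the liver pyruvate kinase, fell by 1.81 and 1.82 at 24 h and 48 h, while Ldha, which makes lactate, rose by 0.74 and 0.82. Of 13 glycolysis genes 5 rose and 2 fell at 24 h and 4 rose and 1 fell at 48 h. Pck1, the entry enzyme of gluconeogenesis, fell by 0.90 at 48 h, and of 10 gluconeogenesis genes 1 rose and 1 fell at 24 h and 3 fell at 48 h. The stress factor Atf3 rose by 2.33 and 3.32, among 5 and 4 of 12 immediate early genes. These genes, each called by edgeR where a rise or fall is given, were chosen after their values were seen, as were those of the next paragraph.

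Cytochromes of drug metabolism split: Cyp2b9 rose by 3.64 and 4.19 at 24 h and 48 h against sham and Cyp2e1 fell by 0.99 and 1.43. Of 18 drug metabolism genes 6 rose and 6 fell at 24 h (3 rose without sham 1 or 3) and 3 rose and 6 fell at 48 h. In 6 of the remaining lists, genes higher and lower than sham were counted at 24 h, then 48 h. TCA cycle (16 genes) had 2 and 3, then 3 and 4. Mitochondrially encoded (13) had 0 and 2, then 0 and 4. Clock (13) had 1 and 0, then 1 and 1. Pericentral hepatocyte (14) had 3 and 3, then 1 and 2. Stellate cell and fibroblast (14) had 1 and 2, then 3 and 2. Cholangiocyte (7) had 0 and 2 at both times. Single libraries moved some of these counts: TCA cycle had 1 higher at 24 h without sham 3, 4 or 5 or PHx24 5, cholangiocyte 1 and 1 at 24 h and 0 and 1 at 48 h without sham 2, and at 48 h mitochondrially encoded genes 1 and 3 without sham 1 or PHx48 2, clock up to 4 lower without sham 4 or PHx48 4, pericentral hepatocyte 2 and 2 without PHx48 5, and stellate cell 2 higher without sham 2 or PHx48 4 and 5 higher without sham 1. The directions of these medians depended on the scaling, as for TCA cycle at 24 h (-0.13 here, 0.10 in TPM). Cholesterol synthesis had 3 of 22 genes higher and 1 lower at 48 h. Among lists with few tested genes, the T and NK cell gene Ccl5 fell at both times, the B cell gene Ighm at 24 h (lost without sham 1 or 2 or PHx24 2, 3, 4, 5, 6 or 7), and 1 of 2 gut epithelium and 1 of 2 mesothelium and gallbladder genes at 24 h. Of 3 exocrine pancreas genes 3 fell at 24 h, and 0 without sham 2. Of 4 adipocyte genes 0 were called by edgeR at either time, and 3 fell at 24 h without PHx24 1.

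With etomoxir at 24 h camera with the preset correlation also called oxidative phosphorylation, TCA cycle, pericentral hepatocyte, sinusoidal endothelial cell, extracellular matrix, interferon response and growth hormone and STAT5 targets lower and ribosome biogenesis higher. The adjusted p of these lists with an estimated correlation was 0.397, 0.447, 0.374, 0.421, 0.508, 0.447, 0.449 and 0.471. Each was lost by fry, and all but oxidative phosphorylation were lost or turned without PHx24_ETO 2. Among their genes edgeR called Igf1 and Cxcl10 lower and the matrix gene Fn1 higher. Igf1 fell by 0.52 and the chemokine gene Cxcl10 by 2.20 (edgeR adjusted p = 0.0479 and 0.0465), in 4 of 4 libraries each, but both calls were lost without PHx24_ETO 2, 3 or 4, among others (highest adjusted p = 0.185 and 0.142), and Cxcl10 was at -1.19 without PHx24 2.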
